A study of Homo sapiens with 21 samples.

How the data were processed

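The series holds miCLIP, RNA-seq and Ribo-seq of MOLM13 cells. Per the labels' protocols, miCLIP used 30 ug of poly(A) RNA per replicate, RNA-seq libraries were strand-specific and made from lysate RNA after removal of ribosomal RNA, and Ribo-seq libraries were made from fragments of 27 to 35 nt left after 30 min in 10 ug/ml micrococcal nuclease. The submitters' processing notes name STAR, Novoalign 3.02.12 and the genome build hg19, with no role given for any of them. The counting program, the annotation, the scaling and the site caller are not given in the sources used here.

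The deposited gene tables hold whole numbers that are scores of scaled reads rather than raw counts. This was tested on the values themselves. Several columns lack regularly spaced whole numbers, as rounding counts multiplied by a factor leaves them, and the factor found from the spacing gave the reads behind each library where it could be found. The deposited miCLIP lists give a score of at least 2 to each site, which is the authors' value per site, and its meaning is not given in the sources used here. The tables also come as 18 sheets of single libraries, whose values all equal the columns used. Of the 1867 gene identifiers, 1848 matched the reference table of gene names, and symbols were taken from the tables.

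Groups followed the labels. For 6 RNA-seq samples the title and the shRNA characteristic contradict the description that names the table column. The description was followed, a choice made before the data were examined, with the title as an alternative.

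The planned test, a quasi-likelihood fit for raw counts, was not used, because the values turned out to be scaled. In its place limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) with the deposited scaling, with an intensity trend and robust empirical Bayes moderation. Genes needed a value of at least 10 in at least 3 libraries, which left 1802 genes in RNA-seq, 1827 in Ribo-seq and 1763 for translational efficiency. The filter and the pseudocount of 1 were chosen after the unit was known and after a fit with no filter had been seen. Contrasts were both hairpins averaged against control, each hairpin against control, and shRNA 12 against shRNA 9. Translational efficiency was the interaction of assay and shRNA in 1 limma model over 18 libraries. All tests were two-sided, with a Benjamini-Hochberg adjusted p under 0.05. Folds are 2 to the power of the fitted log2 fold change, and a value ± SD is on the deposited scale.

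Depth limits the precision. Data were simulated at the depths found from the spacing, with RNA-seq values taken as reads where none was found. In them 200 genes were changed. The RNA-seq spread beyond counting noise was at the lower limit set for it (dispersion 0.0001), and the shares hold for those settings. In the averaged RNA-seq comparison 4-, 2- and 1.5-fold changes were called in 100%, 98.4% and 75.8% of cases. The shares were 100%, 78.5% and 42.4% for Ribo-seq, and 96.7%, 56.5% and 18.8% for translational efficiency. Of the calls made, 9.15% were false in the Ribo-seq comparison of the hairpins and 7.62% in translational efficiency with shRNA 9, above the nominal rate. The estimator of spread in that simulation was changed once, from a median to a trimmed mean, and the self-test passed with both.

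Replicates were compared before averaging. Every pair that could be tested by a chi-square test on reads differed by more than sampling noise, so none was a copy of another. The chi-square per degree of freedom ran from 1.09 to 2.85, so some replicates varied little beyond counting noise. Adjusted p values rest on this spread, and whether it covers variation between separate cultures was not tested. The pairs that could be tested were all 9 of Ribo-seq and 2 of RNA-seq. Residuals of libraries with the same replicate number were uncorrelated (all correlations at most 0.1), so the numbers were not used to pair samples. No batch is named in the labels. Every gene reached at least 6 in RNA-seq and 11 in Ribo-seq in the first control library. No other library shares this minimum, as selection of genes on that library would leave it. Among 449 genes with a Ribo-seq mean under 15 in the other control libraries, the first control library was above that mean in 80.0%. For RNA-seq it was above in 60.2% of 216 such genes, so the selection is less clear there.

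Before the data were examined 23 gene lists were fixed, of which 13 had at least 3 tested genes and 3 (apoptosis inhibitors, cholesterol and lysosome, and mitochondrially encoded genes) had none. Lists were tested with limma's camera with a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Markers of erythroid and lymphoid cells were among the lists. Named genes followed a fixed rule: for each averaged comparison the 10 largest rises and 10 largest falls past the threshold in the same direction with both hairpins, with fully separated libraries in RNA-seq and Ribo-seq, the 4 list members with the smallest p in each assay, and the 5 largest rises and falls between the hairpins. The rule's expression minimum was set at a mean log2(value + 1) of 4, in place of the same number on the scale planned for raw counts. The text names only some of the genes the rule gives, chosen after their values were seen, to limit its length.

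For the hairpin overlap, 100 sets of unchanged hairpin groups were simulated against shared controls. For Ribo-seq against RNA-seq levels, ranks were permuted 2000 times. To match depth between Ribo-seq libraries, the reads found from the spacing were thinned at random to the depth of the shallowest library, in 20 draws, and scaled and rounded again. miCLIP sites were matched by position and strand, with 95% Clopper-Pearson intervals for shares, which cover counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

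Alternatives covered the scaling, the filter, the pseudocount, a replicate block, the groups in the fit, the title labels, the set test and each library left out. Left out were the position of miCLIP sites in genes, their shifted background within genes and the comparison of m6A-marked with other genes, because no genome or annotation of the build hg19 was used here.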

Results

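MOLM13 is an established human acute myeloid leukaemia cell line. METTL3 is the catalytic subunit of the complex that places N6-methyladenosine (m6A) on messenger RNA. The 21 samples formed 7 groups of 3. Of these, 3 libraries were miCLIP, which maps m6A at single nucleotides by crosslinking an antibody to RNA, made from poly(A) RNA of MOLM13 cells. The other 18 came from cells taken 4 days after transduction with a control short hairpin RNA (shRNA) or with 1 of 2 hairpins against METTL3, called shRNA 9 and shRNA 12. Each of these 3 conditions had 3 RNA-seq libraries and 3 Ribo-seq libraries, the latter made from nuclease-protected fragments of 27 to 35 nt. The labels call the replicates biological.

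Both gene tables used here held the same 1867 protein-coding genes. Shares of genes called and list tests below hold within these genes only, not across all protein-coding genes. Values were whole numbers that had been scaled per library, so their sums are not sequencing depth. RNA-seq sums ran from 411447 to 433427. Ribo-seq sums ran from 116411 to 119920 in the libraries labelled control and shRNA 12 and from 159400 to 169310 in those labelled shRNA 9. The spacing of the whole numbers put the reads behind the Ribo-seq values at 141104 to 159019 per library for control, 90133 to 96500 for shRNA 9 and 154622 to 208194 for shRNA 12. METTL3 was not among these 1867 genes, nor were METTL14, MYC and BCL2. The knockdown could therefore not be measured, nor the labels checked by their target.

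The labels of 6 RNA-seq samples conflict. The 3 samples titled METTL3 shRNA 9 have table columns named as control, and the 3 titled control have columns named as shRNA 9. Groups below follow the column names, and RNA-seq and translational efficiency directions are given for that reading. With the groups taken from the titles, 777 of the 1360 genes called in the averaged RNA-seq comparison were called in the opposite direction and 109 in the same direction.

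The first comparison asked which transcripts differed between cells with a METTL3 hairpin and cells with the control hairpin. STMN1 (ENSG00000117632), which encodes the microtubule regulator stathmin, had a mean value of 11.3 ± 3.79 (SD, n = 3) in control, 167 ± 19.9 with shRNA 9 and 349 ± 5.29 with shRNA 12, a 20.3-fold rise. SLC7A11 (ENSG00000151012), the cystine transporter, fell 16-fold, from 1178 ± 57.0 in control to 75.7 ± 20.2 with shRNA 9 and 71.3 ± 6.03 with shRNA 12 (n = 3 each). MEGF9 (ENSG00000106780) fell 12.3-fold, from 1350 ± 61.8 to 131 ± 20.5 and 91.7 ± 8.02. PTGS2 (ENSG00000073756), the inducible cyclooxygenase, fell 8.09-fold, from 1580 ± 33.6 to 370 ± 43.3 and 103 ± 12.2.

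Other large rises were those of HMMR (12.6-fold), the cyclin gene CCNA2 (10.4-fold), the condensin gene NCAPG (9.40-fold), the proliferation marker MKI67 (8.64-fold), INHBA (7.97-fold), HELLS (7.83-fold), the amino acid transporter SLC38A5 (7.79-fold) and THAP4 (7.58-fold). HIST1H4I rose 7.84-fold, a value that is uncertain because H4 histone genes are near-identical copies. Other large falls were those of the kinase gene RPS6KA2 (13.0-fold), the NADPH oxidase gene CYBB (8.52-fold), ERV3-1 (8.34-fold), the calprotectin gene S100A8 (7.73-fold), the transcriptional repressor gene BCL6 (7.41-fold) and NAV3 (6.51-fold). Among these genes the standard errors of the log2 fold changes ran from 0.07 (PTGS2) to 0.21 (INHBA). With limma, 1360 of 1802 tested genes passed a Benjamini-Hochberg adjusted p of 0.05, 750 higher and 610 lower. In 573 genes every library labelled METTL3 shRNA lay above every control library and in 469 below, 57.8% of the genes tested. Chance gives 2.38% for 9 libraries that differ only at random, but any difference between the 3 groups raises this share, and the libraries labelled shRNA 9 lay at one end in 19.1% and those labelled shRNA 12 in 34.0%.

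**Figure D1:**
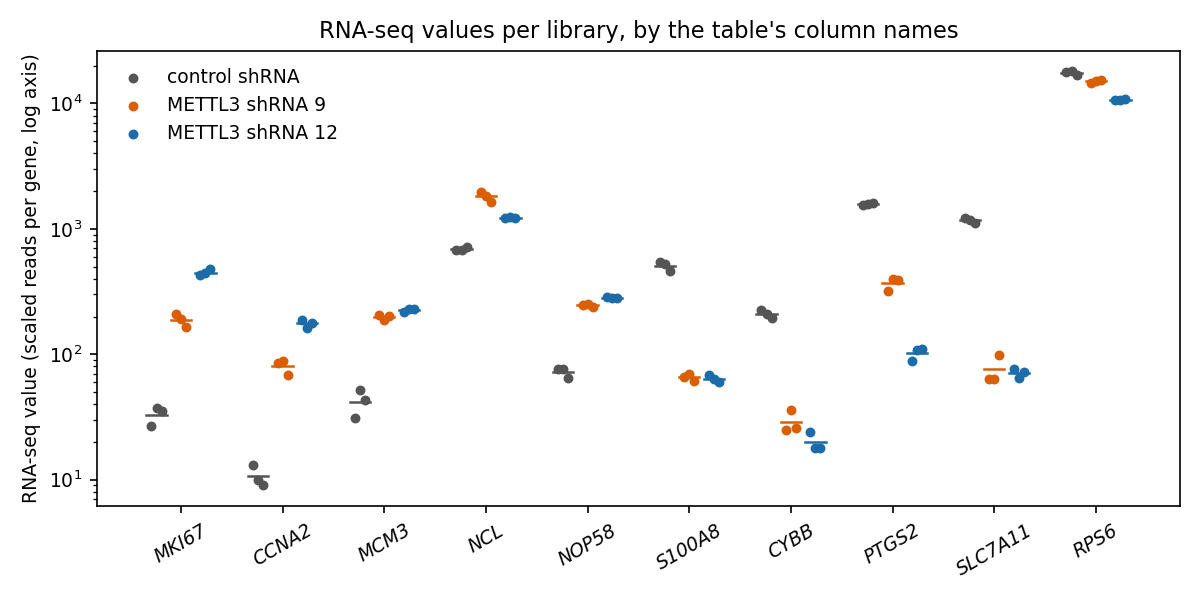
RNA-seq values (scaled reads per gene, log axis) of 10 genes, with 1 point per library, a bar at each mean, and colours for the 3 groups as the column names give them. MKI67 rises from a mean of 33.0 in control to 189 with shRNA 9 and 448 with shRNA 12, while SLC7A11 falls from 1178 to 75.7 and 71.3.

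All 10 tested genes of the 48 on the myeloid differentiation list fell. S100A8 fell by 2.95 on the log2 scale (SE 0.09), CYBB by 3.09 (SE 0.15), MNDA by 2.56 (SE 0.13) and EGR2 by 1.74 (SE 0.08), while the protease gene CTSB fell by 0.80 (SE 0.04). With limma's camera test against all other tested genes the list had an adjusted p = 9.2e-06, and adjusted p = 0.026 with an estimated correlation. With the groups taken from the titles 8 of the 10 rose and 0 fell (camera adjusted p = 2.98e-05, and adjusted p = 0.0365 with an estimated correlation). All 6 tested genes of the 36 on the cell cycle and DNA replication list rose, among them CCNA2 (log2 fold change 3.38, SE 0.14), the transcription factor gene FOXM1 (2.84, SE 0.17) and the replicative helicase gene MCM3 (2.33, SE 0.11). The camera adjusted p of this list was 0.00275, and adjusted p = 0.115 with an estimated correlation. By the titles 1 rose and 4 fell, with a camera adjusted p = 0.339.

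All 10 tested genes of ribosome biogenesis and MYC targets rose. The nucleolar genes NCL, NOP58 and TCOF1 and the growth-related gene PA2G4 had log2 fold changes of 1.11 (SE 0.05), 1.85 (SE 0.08), 2.03 (SE 0.11) and 1.45 (SE 0.09). The list had a camera adjusted p = 5.66e-05, and adjusted p = 0.121 with an estimated correlation. By the titles all 10 fell (camera adjusted p = 2.98e-05, and adjusted p = 0.169 with an estimated correlation). Of 16 tested cytosolic ribosomal protein genes 14 fell and 2 did not pass, with RPS6 lower by 1.39-fold and RPL30 by 1.48-fold. That list had a camera adjusted p = 4.61e-05, and adjusted p = 0.121 with an estimated correlation, and by the titles 12 fell (camera adjusted p = 0.00391, and adjusted p = 0.324 with an estimated correlation). Values of ribosomal protein genes are uncertain because of their many processed pseudogenes.

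Of 6 tested NF-kB and inflammatory genes 4 fell and 2 did not pass. PTGS2 fell 8.09-fold. On the log2 scale the chemokine gene IL8 fell by 1.59 (SE 0.05) and the mitochondrial superoxide dismutase gene SOD2 fell by 1.23 (SE 0.06). The camera adjusted p was 0.00444, and adjusted p = 0.121 with an estimated correlation. By the titles 3 rose and 0 fell (camera adjusted p = 0.117). In the leukaemia self-renewal list ZFP36L2 rose 2.61-fold, MEIS1 1.67-fold and CDK6 1.23-fold, and LMO2 fell 2.54-fold. Of its 6 tested genes 3 rose and 2 fell (camera adjusted p = 0.693). The log2 fold change of CDK6 was -0.16 with shRNA 9 and 0.76 with shRNA 12 (limma adjusted p of the difference 8.58e-18).

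In the integrated stress response list the serine synthesis gene PHGDH rose 6.72-fold, while SLC7A11 and the stress transcription factor gene DDIT3 (3.86-fold) fell. Of its 5 tested genes 3 rose and 2 fell, with a median log2 fold change of 0.68, a mean of -0.25 and a camera adjusted p = 0.996. The translation initiation gene EIF3H rose 2.71-fold. Of 5 translation factor genes 4 rose and 1 fell (camera adjusted p = 0.105). RBM15B, the only gene of the m6A machinery that was tested, fell 1.43-fold. The immediate early gene JUN fell 5.67-fold, the transferrin receptor gene TFRC rose 3.16-fold and CD4 rose 2.98-fold. For all these lists the RNA-seq counts of members past the threshold were the same when adjusted over the list alone.

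Against control, the libraries labelled shRNA 9 and shRNA 12 each differed widely from control in RNA-seq. MKI67 was higher by 2.49 on the log2 scale with shRNA 9 and by 3.74 with shRNA 12, and S100A8 was lower with each (-2.94 and -2.97). JUN had log2 fold changes of -2.41 and -2.59, and NOP58 of 1.75 and 1.95. In limma 1255 genes were called with shRNA 9 (685 higher, 570 lower) and 1339 with shRNA 12 (745 higher, 594 lower). Of these, 570 were higher and 451 lower with both, where lists drawn independently would share 283 and 188, and 49 were called in opposite directions.

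Across the 1802 genes the log2 fold changes of the hairpins had a Pearson correlation of 0.87. Sharing the control libraries gave 0.50 in simulation of unchanged groups. The covariance of the changes was 0.938 against a simulated 0.0163. Genes are not independent replicates, so no p is given. A high covariance arises from any difference that sets the libraries in the control columns apart from both other groups.

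**Figure D2:**
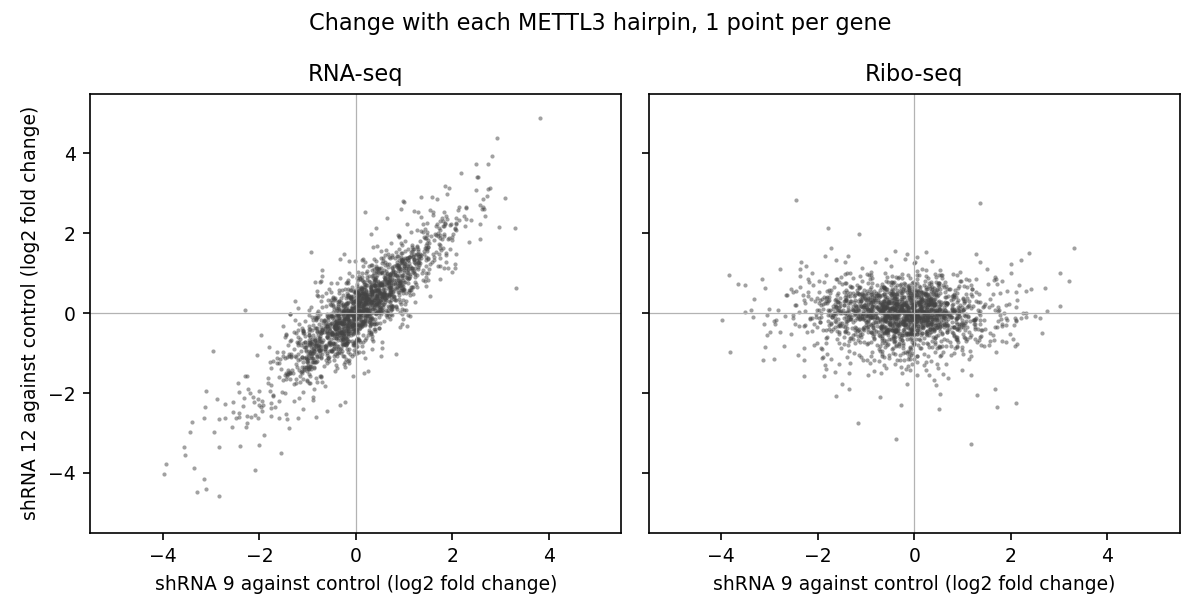
Log2 fold change against control with shRNA 9 (horizontal axis) and with shRNA 12 (vertical axis), 1 point per gene, for RNA-seq (left) and Ribo-seq (right). The RNA-seq changes lie along the diagonal (Pearson correlation 0.87) and the Ribo-seq changes do not (-0.02).

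The hairpins also differed from each other in RNA-seq, in a direct comparison in which the control cancels. With shRNA 12 against shRNA 9 the growth factor gene PDGFA was higher 5.52-fold, the integrin gene ITGA6 5.23-fold, NCKAP1 5.06-fold, DDIT3 4.01-fold and the ubiquitin ligase gene SKP2 3.52-fold. FGL2 was lower 6.37-fold, the chemokine receptor gene CXCR2 4.01-fold and PCNXL2 3.96-fold. ITGA6 had values of 442 ± 21.7 in control, 89.0 ± 7.00 with shRNA 9 and 469 ± 13.3 with shRNA 12 (SD, n = 3). FGL2 had values of 44.3 ± 4.73, 448 ± 48.4 and 69.3 ± 5.13.

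Ribosomal protein genes were lower with shRNA 12 than with shRNA 9 in 15 of 16 cases (camera adjusted p = 3.72e-12, and adjusted p = 0.079 with an estimated correlation). Against control, 15 of them fell with shRNA 12, while 8 fell and 1 rose with shRNA 9. Cell cycle genes were higher with shRNA 12 in 5 of 6 cases (camera adjusted p = 0.00497, and adjusted p = 0.111 with an estimated correlation). NF-kB and inflammatory genes were lower in 4 of 6 cases (camera adjusted p = 0.0351, and adjusted p = 0.245 with an estimated correlation). In limma 838 genes differed, 426 higher and 412 lower with shRNA 12.

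Ribo-seq levels did not follow RNA-seq levels. Across 1867 genes the mean Ribo-seq value was unrelated to the mean RNA-seq value (Spearman correlation -0.0278; the central 95% of 2000 permutations ran from -0.0456 to 0.0458). The 16 ribosomal protein genes of the fixed list, whose mRNAs are abundant and heavily translated, had a median RNA-seq value of 3504 against 96.8 for all genes. Their median Ribo-seq value was 20.1 against 24.8 for all genes. Ribo-seq and translational efficiency values are therefore given under the gene names the table carries, and that the fragments came from those genes was not shown.

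**Figure D3:**
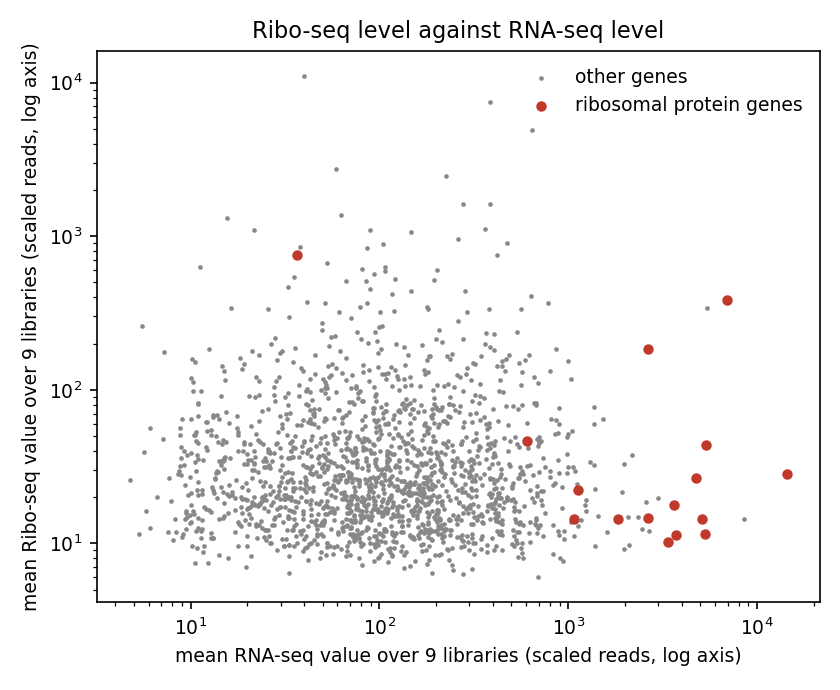
Mean Ribo-seq value (vertical) against mean RNA-seq value (horizontal), both in scaled reads on log axes, 1 point per gene tested in both assays, with ribosomal protein genes in red. Most ribosomal protein genes lie far to the right without lying higher than other genes, and the Spearman correlation over all 1867 genes is -0.0278.

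The Ribo-seq comparison asked which genes gained or lost protected fragments with the METTL3 hairpins. Under the table's names, C3orf80 (ENSG00000180044) rose 5.54-fold, from 2360 ± 148 in control to 23531 ± 4455 with shRNA 9 and 7353 ± 555 with shRNA 12 (SD, n = 3). It was the highest gene in each library of both hairpins. It held 12.3% to 16.8% of the summed values with shRNA 9 and 5.68% to 6.54% with shRNA 12. TMEM43 rose 4.15-fold, MARVELD1 4.06-fold, PHACTR4 4.01-fold and KIAA0232 3.82-fold. ERV3-1 (ENSG00000213462) fell 4.45-fold, from 78 ± 7.81 to 8.67 ± 4.73 and 34.0 ± 3.00, and the DNA polymerase gene POLD3 fell 4.08-fold. C2orf69 fell 3.33-fold, TDP2 3.12-fold and FAM208B 2.98-fold.

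SP1, a transcription factor gene, rose 2.08-fold in Ribo-seq, with log2 fold changes of 1.90 with shRNA 9 and 0.21 with shRNA 12 (limma adjusted p = 5.2e-06 and 0.623; for the difference between hairpins, adjusted p = 1.5e-05). HOXA3 rose 1.87-fold, BCL6 1.60-fold, FOXM1 1.49-fold and RPL41 1.37-fold, and CDK6 fell 5.26-fold and PA2G4 1.80-fold. CCNA2 fell 3.24-fold (log2 fold change -1.70, SE 0.47, limma adjusted p = 0.011), with -3.11 for shRNA 9 and -0.28 for shRNA 12. Its call was lost without control replicate 1 (-1.69, adjusted p = 0.0583) and without control replicate 3 (-1.55, adjusted p = 0.0886).

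By list, 2 of 6 cell cycle genes rose and 1 fell, 2 of 10 myeloid genes fell, 1 of 10 ribosome biogenesis genes rose and 2 fell, and 3 of 16 ribosomal protein genes rose and 2 fell. Adjusted over the list alone, 3 ribosomal protein genes fell, and the counts of the other 3 lists were the same. With upper-quartile scaling 2 ribosomal protein genes rose and 3 fell, and with median-of-ratios or trimmed-mean scaling 1 myeloid gene fell. With the deposited scaling the median log2 fold change was below 0 in all 13 lists with at least 3 tested genes, while camera's direction was up in 6 of them, and with median-of-ratios scaling the median was above 0 in 7. In the averaged comparison none of these lists passed limma's camera test, nor with an estimated correlation or with fry. At an unadjusted p under 0.05 the counts were 0, 0 and 2. In limma 550 of 1827 genes passed in the averaged comparison, 224 higher and 326 lower. Groups were fully separated in 95 genes upwards and 137 downwards, 12.7% of the genes tested, where chance gives 2.38% for libraries that differ only at random. The libraries of shRNA 9 lay at one end in 44.7% and those of shRNA 12 in 23.8%, so the 12.7% is not evidence of a change shared by the hairpins. The median log2 fold change was -0.12 with the deposited scaling and -0.02 with median-of-ratios scaling, which gave 292 higher and 257 lower.

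The Ribo-seq changes of the hairpins were uncorrelated across genes. With shRNA 9, 955 genes were called (358 higher, 597 lower), among them FOXM1, CDK6, PA2G4, CCNA2, HOXA3 and RPL41. With shRNA 12, 397 were called (197 higher, 200 lower), and none of these 6 genes was among them. In fits of only the 2 groups compared the counts were 876 and 638. The difference between the hairpins had a limma adjusted p of 0.00034 for FOXM1, 0.000131 for CDK6, 9.77e-09 for PA2G4, 0.000239 for CCNA2, 0.00342 for HOXA3 and 5.3e-05 for RPL41. Both hairpins called 64 genes higher and 55 lower, where independent lists would share 38.6 and 65.4, and 134 were called in opposite directions, where independent lists would give 104. The Pearson correlation of the log2 fold changes was -0.02. Sharing the controls gave 0.50 in simulation, but with unchanged groups, so that value is no measure for groups with many called genes. On the covariance scale the observed value was -0.0133, against 0.0363 from sharing the controls.

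Compared directly, shRNA 12 against shRNA 9, 1068 Ribo-seq genes differed in limma, 645 higher and 423 lower (546 and 518 with median-of-ratios scaling). FANCG was higher 38.7-fold, OTUD3 27.5-fold and HPS3 21.1-fold, and GMNN was lower 21.9-fold, TEC 20.4-fold and SLC35A2 11.8-fold. The log2 fold change of FANCG, 5.27, was 4.39 without shRNA 9 replicate 1 and 5.89 without shRNA 9 replicate 2. HPS3 had values of 134 ± 10.0 in control, 10.0 ± 3.61 with shRNA 9 and 223 ± 16 with shRNA 12 (SD, n = 3), and TEC had 84.7 ± 13.1, 369 ± 62.2 and 17.0 ± 1.00. In the libraries labelled shRNA 9 the 10 highest genes held 37.6% to 40.2% of the summed values, against 19.5% to 22.8% in the other 6 Ribo-seq libraries. The median log2 fold change with shRNA 9 was -0.21 with the deposited scaling and -0.03 with median-of-ratios scaling, so calls lower with shRNA 9 (597) became 480 and calls higher (358) became 454.

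Translational efficiency was taken as the Ribo-seq change minus the RNA-seq change, tested as an interaction in limma. MEGF9 rose 22.2-fold in this measure, PTGS2 14.3-fold and BCL6 11.8-fold, and STMN1 fell 27.4-fold, HIST1H4I 16-fold, HMMR 13.6-fold, the isoleucyl-tRNA synthetase gene IARS 9.62-fold and the purine synthesis gene PAICS 7.84-fold. Most of this size came from RNA-seq. STMN1 had a Ribo-seq log2 fold change of -0.43 (SE 0.26) beside an RNA-seq log2 fold change of 4.35 (SE 0.14), and MEGF9 had 0.86 (SE 0.25) beside -3.62 (SE 0.08).

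Myeloid genes rose in translational efficiency in 7 of 10 cases (8 when adjusted over the list alone; camera adjusted p = 5.59e-05, and adjusted p = 0.00552 with an estimated correlation). Cell cycle genes fell in 5 of 6 cases (6 when adjusted over the list alone; camera adjusted p = 0.00707, and 0.0461 with an estimated correlation). Ribosome biogenesis genes fell in 9 of 10 cases (camera adjusted p = 0.00142) and NF-kB genes rose in 4 of 6 (camera adjusted p = 0.0142). In averaged Ribo-seq none of these lists passed. The calls here thus came mainly from the RNA-seq changes of the same lists, taken with the opposite sign, and are not separate evidence of changed translation. With the RNA-seq groups taken from the titles 3 of these 4 calls were lost, with camera adjusted p = 0.621 for cell cycle genes (2 rose), 0.0654 for ribosome biogenesis genes (6 rose) and 0.756 for NF-kB genes (2 fell). That of the myeloid genes turned, with 7 of 10 lower (camera adjusted p = 0.0125, and adjusted p = 0.0623 with an estimated correlation). The cell cycle list had a camera adjusted p = 0.0969 with shRNA 9 and 0.00221 with shRNA 12. Of the NF-kB genes 2 rose and 2 fell with shRNA 9 (camera adjusted p = 0.516) and 4 rose with shRNA 12 (0.0042). Differences between the hairpins were not tested in this measure. In limma 1018 of 1763 genes passed in the averaged comparison (391 higher, 627 lower), 1071 with shRNA 9 (394 higher, 677 lower) and 953 with shRNA 12 (410 higher, 543 lower).

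Across genes, translational efficiency changes correlated with RNA-seq changes at a Pearson correlation of -0.87, and Ribo-seq with RNA-seq changes at 0.01. Of the genes called in both assays, 396 where 399 would be expected by chance, 198 moved in the same direction and 198 in opposite directions. The tables were scaled separately, so only changes, not levels, enter this measure. With median-of-ratios scaling the median log2 change in this measure went from -0.22 to -0.03, and the averaged calls became 488 higher and 502 lower.

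The miCLIP comparison asked where m6A was called and how well replicates matched. The deposited lists held 8113, 2866 and 2050 sites in replicates 1, 2 and 3, each a single nucleotide with a 5-mer and a score. Every 5-mer was one of the 18 sequences of the DRACH motif (D is A, G or T; R is A or G; H is A, C or T), so the lists had been filtered on it. Replicates 1 and 2 shared 627 sites at the same position and strand (21.9% of the smaller list, 95% Clopper-Pearson interval 20.4% to 23.4%). Replicates 1 and 3 shared 555 (27.1%, 25.2% to 29.1%) and replicates 2 and 3 shared 237 (11.6%, 10.2% to 13.0%). After a shift of 100 nt these pairs shared 3, 2 and 1 sites.

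Of 11746 distinct sites 1147 (9.77%) were found in at least 2 replicates and 136 in all 3. The GGAC core was found at 33.3% of distinct sites (32.4% to 34.1%). It was found at 40.1% of sites in at least 2 replicates and 32.6% of sites in 1 (Fisher's exact test, two-sided, odds ratio 1.39, p = 3.65e-07), and at 50% of sites in all 3. GGACA (15.2%) and GGACT (13.3%) were the most frequent 5-mers. Sites scoring above their replicate's median of 2 were found again in 26.5%, 50.4% and 59.4% of cases, against 8.19%, 19.1% and 25.0% of the others.

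The highest sites found in all 3 replicates, chosen after their values were seen, were on chromosome 2 at 133011957 on the minus strand (TAACA, scores 220, 218 and 129), chromosome 11 at 85195068 on the plus strand (AAACT, scores 57, 35 and 32) and chromosome 7 at 5567374 on the minus strand (GGACT, scores 41, 31 and 38). Coordinates are those of the deposited lists. The submitters' processing notes name hg19, and genes at these positions were not analysed here. Scores are the authors' values per site, and intervals cover counting error only.

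**Figure D4:**
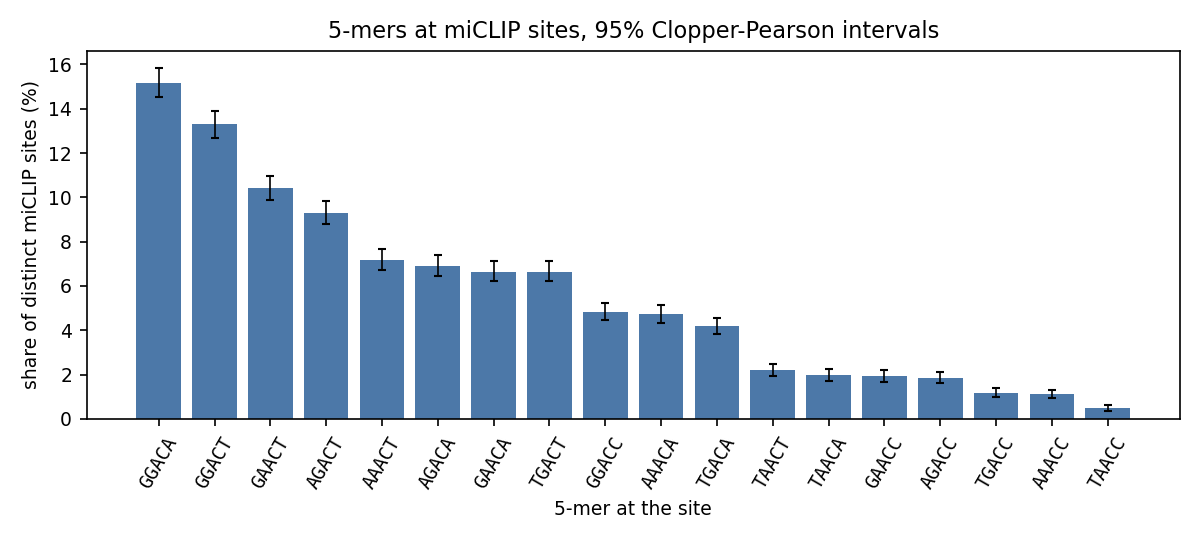
Share (%) of the 11746 distinct miCLIP sites with each 5-mer of the motif, with bars from 0 and lines for 95% Clopper-Pearson intervals. GGACA (15.2%) and GGACT (13.3%) lead.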

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

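Of the tests below, those of the title reading, the scaling, the knockdown, shifted tables, the gene names, a few dominant genes and depth, and the splits of Ribo-seq libraries alone in translational efficiency, were chosen after the result was seen, and those of low values, the first control library and all remaining splits before.

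The hairpins differed from each other when tested directly. In RNA-seq 838 genes differed between shRNA 12 and shRNA 9, and in Ribo-seq 1068.

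The libraries in the RNA-seq control columns stood apart from both hairpin groups. If the titles were right, those libraries would carry shRNA 9, and the covariance of the hairpins' changes would exceed the value from shared controls by more under the titles. Under the titles it lay at -0.0156 from that value (bootstrap interval -0.0428 to 0.0130), and under the column names 0.922 above it, which follows whenever the control columns stand apart, whatever they hold. Scaling as the whole cause is argued against, since 1283 of 1360 genes were called again in the same direction with median-of-ratios scaling. That test is mild, because this scaling moved the median log2 fold change of the myeloid list only from -1.38 to -1.47. A factor per library moves all its genes the same way, while 285 genes were called at least 2-fold higher and 200 at least 2-fold lower. Exchanged labels and METTL3 knockdown cannot be told apart here, because METTL3 was not among the genes used.

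Ribo-seq levels were unrelated to RNA-seq levels. Tables shifted against each other are argued against by a largest absolute Spearman correlation of 0.0759 over 1866 shifts. Among 456 genes with a mean Ribo-seq value of at least 50 the correlation was 0.0897 (upper 95% bound 0.183, with genes taken as independent). It argues only weakly against low values as the cause, because choosing genes by their Ribo-seq value narrows the range and can itself lower a correlation. A candidate explanation is that the Ribo-seq values do not belong to the gene names beside them: the median Ribo-seq value of the 16 listed ribosomal protein genes was at percentile 19.38 of 10000 random lists, while their RNA-seq median was at percentile 100. That test first ran on 20 genes matched by name prefix, kinase genes included (percentile 48.08), and was changed to the fixed list after its result was seen. No biological explanation was tested.

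More genes were called in Ribo-seq with shRNA 9 (955) than with shRNA 12 (397), but 876 and 638 in fits of only the 2 groups compared. At the libraries' own depths the size of this difference thus depends on fitting all 3 groups together. With the reads per unit of value matched, as given below, it depended on this less. In the fit of 3 groups, a few genes taking most of the reads are argued against as the whole cause by a ratio of calls of 2.40 with median-of-ratios scaling, and selection of genes on the first control library by a ratio of 3.05 without it. Lower depth as the whole cause is argued against by thinning all 9 libraries to the fewest reads per unit of value. The median ratio was then 2.71 (2.54 to 3.00 over 20 draws), and 2.29 (2.11 to 2.64) in fits of 2 groups. Summed reads were not matched. After thinning they were highest with shRNA 9, so its libraries were no longer the shallowest. A difference between the hairpins remains a hypothesis, found and tested on the same data, and the unexplained gene names above apply to it.

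Other splits of the same libraries were fitted with 2 groups. In RNA-seq there were 84 splits of 3 against 6 libraries. Only 1, that of the column names, called as many genes as the averaged comparison by those names (1108, highest other 358). The next highest, 358 and 136, set the shRNA 12 and the shRNA 9 columns against the rest, and splits that mixed the groups called fewer. The rank therefore shows only that the control columns stood apart most. It cannot say whether chance, a batch or the hairpins set them apart. By the titles the averaged split sets the shRNA 9 columns against the rest, which called 136, with 2 other splits above it (1108 and 358). In Ribo-seq 3 of 84 splits called as many genes as the real one. The real split called 19 genes in that fit, while setting shRNA 9 against the rest called 964 and shRNA 12 against the rest 171, so a structure of the samples outweighs the averaged comparison. For translational efficiency by the column names, 1 of 100 splits of both assays, the real one, reached the averaged result (560; highest other 454), the shRNA 9 result (1014; highest other 999) and the shRNA 12 result (1097; highest other 789). With the RNA-seq grouping kept and only the Ribo-seq libraries split, 3 of 84 splits reached the averaged result (highest other 1012), and 1 of 20 that of shRNA 9 (highest other 999) and of shRNA 12 (highest other 1048), where 20 are too few for a share under 0.05. Each of these splits called at least 332, 270 and 731 genes, so part of each count comes with the RNA-seq grouping alone. For each comparison of 3 with 3 libraries there are 10 splits, too few for a share under 0.05, and 1, the real one, reached its own count. These counts were 1223, 1374 and 828 in RNA-seq for shRNA 9, shRNA 12 and their difference, and 876, 638 and 989 in Ribo-seq, with a highest other of 0 in each.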

How the results depend on the processing

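Of the alternatives below, trimmed-mean scaling, the pseudocounts of 0.5 and 4 and the mean of at least 30 were chosen after seeing the data. For named genes, 1738 of 1798 values over 91 results kept their direction and their side of the threshold, 6 kept their direction and lost the call, and 54 reversed, 0 of them outside the title labels. For 16 counts, 339 of 353 values stayed within 1.5 times the reported count and 14 moved.

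With the groups of the RNA-seq samples taken from the titles, log2 fold changes in the averaged RNA-seq comparison reversed to STMN1 -1.37, HMMR -0.73, CCNA2 -0.84, NCAPG -0.87, MKI67 -0.62, INHBA -1.65, HIST1H4I -0.83, HELLS -0.81, SLC38A5 -1.21, THAP4 -1.19, SLC7A11 1.96, RPS6KA2 0.55, MEGF9 1.43, CYBB 1.16, ERV3-1 2.04, PTGS2 0.13, S100A8 1.45, BCL6 1.84, NAV3 1.13, CTSB 0.84, EGR2 0.17, MCM3 -1.03, FOXM1 -0.41, NCL -0.97, NOP58 -0.78, TCOF1 -0.58, PA2G4 -0.49, IL8 0.67, SOD2 0.29, ZFP36L2 -0.56, LMO2 0.080, PHGDH -1.19, DDIT3 2.48, TFRC -0.50, CD4 -1.24, EIF3H -1.12, JUN 1.12, RBM15B 0.24, IFI16 -0.87, BTG2 0.98, PHLDA3 -0.44, TNFRSF10B 0.45, EDEM1 -0.71, HIST1H1B -0.52, MEIS1 -0.12, MNDA 1.18. Between the hairpins they reversed to DDIT3 -0.94, FGL2 0.64, and in translational efficiency to MEGF9 -0.57, BCL6 -1.17, STMN1 0.94, HMMR 0.63, IARS 0.65, PAICS 0.99. Of these reversed values PTGS2 (adjusted p = 0.121), EGR2 (0.079), LMO2 (0.266) and MEIS1 (0.403) in RNA-seq, and MEGF9 (0.0715), HMMR (0.12) and IARS (0.119) in translational efficiency, did not pass the threshold. Calls were lost for IL7R (0.15), for ITGA6 between the hairpins (0.085), and in translational efficiency for PTGS2 (0.69) and HIST1H4I (-0.20). The averaged RNA-seq comparison called 1035 genes. The count with shRNA 12 became 838 and that between the hairpins 1339, the shared calls 308, translational efficiency with shRNA 12 504, and its list tests 1 of 13. In RNA-seq 4 lists passed instead of 5, with the direction of myeloid and ribosome biogenesis genes reversed and apoptosis effectors added. Exchanging 2 of the 3 groups gives these changes by construction.

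With a mean of at least 30, Ribo-seq with shRNA 9 called 545 genes and the direct comparison 568, and translational efficiency 443 (averaged), 454 (shRNA 9) and 424 (shRNA 12). Fewer genes were tested, 795 in Ribo-seq and 626 for translational efficiency. With only the 2 groups compared, Ribo-seq with shRNA 12 called 638 genes, and the cause was not tested. With an estimated correlation camera called 1 RNA-seq list instead of 5, and fry called 11 in RNA-seq and 10 in translational efficiency instead of 4. Fry tests against no change rather than against other genes. The share of GGAC was 40.1% among sites in at least 2 replicates and 38.5% among sites scoring above their replicate median, and the cause was not tested. Within 5 nt, 141 sites were in all 3 replicates.

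With the replicate number as a replicate block, RNA-seq called 1360 (averaged), 1252, 1341 and 835 genes and Ribo-seq 544, 942, 376 and 1060. Translational efficiency called 1003, 1062 and 940 with a block per assay, 1004, 1068 and 943 with a block per lysate, and 941, 1039 and 888 from ratios. The numbers were not shown to pair the samples.

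Leaving out 1 library at a time, RNA-seq called 1237 to 1372 genes (averaged), 1137 to 1241 (shRNA 9), 1238 to 1361 (shRNA 12) and 739 to 850 (between hairpins), with 913 to 1014 shared. Ribo-seq called 374 to 646, 810 to 982, 267 to 452 and 935 to 1053, with 81 to 133 shared, and translational efficiency 902 to 1071, 981 to 1102 and 848 to 1020. The list tests stayed at 5, 0 and 4. CCNA2 lost its Ribo-seq call without control replicate 1 (-1.69, adjusted p = 0.0583) and without control replicate 3 (-1.55, adjusted p = 0.0886). Its adjusted p ran from 0.000186 to 0.0886 over the alternatives, and the cause was not tested. Sites in both remaining miCLIP replicates numbered 237 without replicate 1, 555 without replicate 2 and 627 without replicate 3, against 136 in all 3, because fewer lists had to share a site, and the share of GGAC ran from 33.1% to 35.1%.

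Median-of-ratios scaling moved the share of higher calls from 40.7% to 53.2% in averaged Ribo-seq and from 38.4% to 49.3% in translational efficiency, so the balance of directions depends on the scaling there. Not run were the Wald test planned for raw counts, because the values are scaled, and the alternatives for m6A-marked genes, for the position of sites in genes and for a shifted background within genes, because no genome or annotation of the build was used here. Depth limits small changes most in translational efficiency, where 18.8% of simulated 1.5-fold changes were called.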

Other observations

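Values here are from RNA-seq by the column names, in the averaged comparison unless a hairpin is named, for lists fixed before the data were examined. The fit replaced the planned one once the values were known to be scaled. Its filter and pseudocount were set after a fit with no filter had been seen. The genes named were chosen after their values were seen. Among interferon response genes IFI16 rose 2.28-fold and IFIT1 fell 2.88-fold (log2 fold change -0.60 with shRNA 9, -2.45 with shRNA 12, limma adjusted p of the difference 2.39e-06), and of 5 tested 1 rose and 2 fell (camera adjusted p = 0.693). Among p53 targets PHLDA3 rose 1.70-fold and BTG2 fell 1.82-fold, with 1 of 6 higher and 3 lower (camera adjusted p = 0.305). Of 4 apoptosis effector genes 3 fell, among them the death receptor gene TNFRSF10B (1.57-fold), with a camera adjusted p = 0.109. All 4 fell with shRNA 9 (camera adjusted p = 0.0204, and adjusted p = 0.0939 with an estimated correlation). With shRNA 12, 1 rose and 2 fell (camera adjusted p = 0.482). By the titles 3 rose in the averaged comparison (camera adjusted p = 0.0195, and adjusted p = 0.169 with an estimated correlation). Of 3 genes of the PI3K-AKT and FOXO list 2 fell, BCL6 by the most, and with median-of-ratios scaling 3 fell.

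Of 6 replication-dependent histone genes 4 rose (3 with median-of-ratios scaling) and 1 fell, with HIST1H1B higher 3.20-fold. Histone values are uncertain because of near-identical copies, and the list had a camera adjusted p = 0.386. Lists with fewer than 3 tested genes had no set test. Both unfolded protein response genes rose, EDEM1 2.15-fold. On the list of lymphoid markers CD4 and IL7R (1.71-fold) rose, and on that of erythroid and megakaryocyte markers TFRC rose. No other genes of these 2 lists were tested, so these rises do not show a change of lineage. Of 2 immediate early and heat shock genes 1 rose and 1 fell. The only gene tested of the azurophil granule and promyelocyte list, MS4A3, rose with shRNA 9 (log2 fold change 1.07) and fell with shRNA 12 (-0.32). SP1, the only gene tested of a list of candidate translation targets, did not pass the test in RNA-seq (log2 fold change 0.09).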
